A study of Mus musculus with 8 samples.

How the data were processed

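The samples were 8 RNA sequencing libraries of mouse embryonic fibroblasts, 4 control and 4 PUS10KO, grouped by their titles. Per the labels, cells were grown in DMEM with serum and antibiotics, total RNA was extracted with a commercial kit, and stranded total RNA libraries were sequenced in paired-end mode on a NextSeq instrument. The authors deposited whole-number counts of reads per gene, 1 column per library, not normalized. The submitters' processing notes name STAR 2.7.8a, DESeq2 and the mm10 build; the read counter, its strand setting, the annotation and the filter on genes are not given in the sources used here, so genes that overlap an antisense or neighbouring gene cannot be told from it by these counts. The lowest total of a row over the 8 libraries was 27 counts, and 23 rows had under 10 counts in every library, so genes of low abundance were largely left out before deposit. The authors also deposited a normalized table, which by its values is on a log2 scale (5.13 to 18.12); no source used here states that scale. In it the sum of the PUS10KO and control values of each number was equal for all 12211 genes (tolerance 1e-06), so differences between numbers had been removed.

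Total counts were 23217332, 19724359, 18850689 and 20524947 in control libraries 1 to 4 and 18181054, 24563499, 21904901 and 17561114 in PUS10KO libraries 1 to 4. No 2 libraries of a genotype agreed within sampling noise (lowest chi-square per degree of freedom 17.93), so each counted as 1 sample. That does not show that the libraries came from separate cultures, lines or animals. Gene positions came from GENCODE M21 (GRCm38, the assembly of mm10), matched by symbol for 12048 rows and through a RefSeq synonym for 122, or 99.7% of the rows; 41 rows had no match, and 2 symbols stood on 2 rows. Xist and some other genes were not analysed here.

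Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Low-count genes were removed with filterByExpr, libraries were scaled by TMM, and genotypes were compared with edgeR's quasi-likelihood test (robust), with Benjamini-Hochberg adjustment over 11909 genes and an adjusted p threshold of 0.05. All 8 libraries entered the fit with genotype as the only term. A rise or fall means an adjusted p under 0.05; at least 2-fold means in addition an absolute log2 fold change of at least 1. CPM values are TMM-scaled, with mean ± SD over 4 libraries. Where a gene had 0 counts in a whole genotype, the fold was computed against a floor of 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio has an exact 95% counting interval. Floors and intervals cover counting error only.

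Gene lists, 46 in all, were fixed before the data were examined, with their kinds: study question, pathway, tissue, sample composition and other cell types. They were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the 43 lists with at least 3 tested members. Checks used an estimated correlation and fry, which tests a list by itself. An estimated correlation left 1 list called, the Y-linked genes, with 5 lists at an unadjusted p under 0.05. The lists of germline and pluripotency genes (2 tested), erythroid markers (0) and small structured RNAs and their hosts (1) were too small. Called genes were compared between chromosomes with two-sided Fisher's exact tests. The genes named were also fixed by rule: Pus10; the 10 with the largest rise and the 10 with the largest fall among called genes with a mean log2 CPM of at least 1 and no overlap between genotypes; the Y-linked genes; and in each list up to 4 called members by lowest p (6 in study question lists), or 2 by level where none was called. That the members of all tested lists would be named, and not of some, was settled after first results had been seen. Predicted genes and clones were left out, 10 of 562 eligible genes that rose and 18 of 739 that fell. Any other gene is said to have been named after its values were seen.

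The labels number the libraries 1 to 4 in both genotypes without saying what a number shares. Deviations from the genotype means correlated between libraries of the same number (r = 0.681, 0.722, 0.633 and 0.687 across genes, which are not independent replicates), and all 8 libraries matched their own number best, so the numbers were taken to pair the libraries. For PUS10KO libraries 1 to 4 the highest r with a control library of another number was 0.303, 0.042, 0.582 and 0.503. Numbers 3 and 4 were thus parted less clearly by the counts. The pairing comes from the counts and from the deposited normalized table, not from the labels. The fit without the replicate block stayed the main one, as fixed before the data were examined, and paired values are given beside results that they change.

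The test was tested on simulated data for the comparison of PUS10KO with control. Of 11909 genes 200 were changed, and the members of a list were raised 1.5-fold besides. All were drawn from genes with a mean log2 CPM over 1. The simulated libraries had the spread of the fit without the block, no pairing and no correlation between genes. Of the 200 genes, 1.5% of those changed 1.5-fold were called, 40.3% of those changed 2-fold and 90.9% of those changed 4-fold. Of the unchanged genes 5 were called (5.3% of calls). Alternatives were DESeq2 1.42.0, limma voom, RLE and upper-quartile scaling, no low-count filter, a stricter filter of 1 CPM in 4 libraries, the replicate block, offsets for GC content and gene length with and without the block, removal of 7 mitochondrial and structured RNA genes, removal of each library in turn, and limma-trend on the deposited normalized values. Those values were already on a log2 scale with the differences between numbers removed, so the planned logarithm after adding 1 was not taken and the block was kept in that fit. Added after the data were seen were fits without chromosomes 12, X and Y, fits of the libraries numbered 1 and 2 or 3 and 4 alone, DESeq2 with the block, and camera with an estimated correlation and the block.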

Results

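RNA sequencing counts were analysed for mouse embryonic fibroblasts, connective tissue cells grown from embryos, of 2 genotypes. There were 4 control libraries and 4 libraries labelled PUS10KO, numbered 1 to 4 in each genotype. PUS10 is a pseudouridine synthase, an enzyme that isomerises uridine in RNA, and the title of the series links it to tRNA fragments, retrotransposons and inflammation. Total counts ran from 17561114 in PUS10KO 4 to 24563499 in PUS10KO 2. The table held 12211 genes, of which 11909 had enough counts to be tested. The first principal component held 56.1% of the variance and parted the genotypes, and the second held 26.1% and parted the libraries numbered 1 and 2 from those numbered 3 and 4. The labels do not say that the libraries came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

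The targeted gene was lower in every PUS10KO library. Pus10 (ENSMUSG00000020280.12, chromosome 11, 23665674 to 23732876, plus strand, GRCm38) had 40.9, 51.6, 40.1 and 51.8 CPM (counts relative to the TMM-scaled library total) in control libraries 1 to 4, and 14.3, 15.2, 14.2 and 11.5 CPM in PUS10KO libraries 1 to 4. The means were 46.1 ± 6.46 CPM in control and 13.8 ± 1.60 CPM in PUS10KO (SD, n = 4 each). The log2 fold change was -1.74 (SE 0.15, adjusted p = 0.000189, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The part of the gene that was targeted is not given in the sources used here, and reads remained in all 4 PUS10KO libraries. None of the 20 tested neighbours of Pus10 on its chromosome passed the same edgeR test, 2 had an unadjusted p under 0.05, and DESeq2 called 1 and limma voom 0. With the replicate block 5 of these neighbours rose and 1 fell, where 39% of all genes tested passed. Cct4, a chaperonin subunit, had a log2 fold change of 0.24 (adjusted p = 0.311, or 0.0485 with the block). Xpo1, a nuclear export receptor, had 0.25 (adjusted p = 0.545, or 0.0398 with the block). Relative to the median of chromosome 11 (0.16) these fold changes were 0.08 and 0.09.

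The genotypes also differed in Y-linked transcripts. Eif2s3y, a translation initiation factor subunit gene of the Y chromosome, had 70.0 ± 3.22 CPM in PUS10KO and 0 counts in all 4 control libraries, at least 1999-fold higher against a floor of 3 counts over the group. The histone demethylase genes Uty and Kdm5d had 4579 and 4605 counts over the PUS10KO libraries and 1 and 2 counts over the control libraries. These are ratios of 4585 (exact 95% counting interval 823 to 181100) and 2305 (638 to 19040). All 3 tested Y-linked genes rose, also when adjusted over the list alone (camera adjusted p = 1.41e-62, and adjusted p = 0.00201 with an estimated correlation). With the replicate block the adjusted p was 0.147 with an estimated correlation. Of 5 tested genes known to escape X inactivation 2 fell, and 3 when adjusted over the list alone. With the block 3 fell and 1 rose, and the list was not called (camera adjusted p = 0.326 without and 0.301 with the block). Kdm5c went from 153 ± 8.93 to 108 ± 1.82 CPM (log2 fold change -0.51, adjusted p = 0.00917). Eif2s3x had a log2 fold change of -0.63 (adjusted p = 0.0465), and its call was lost in 6 of 8 fits that left out 1 library, all except those without control 3 or PUS10KO 1 (adjusted p up to 0.128). Sex chromosome content and genotype therefore coincided in all 8 libraries. Xist was not analysed here.

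**Figure D1:**
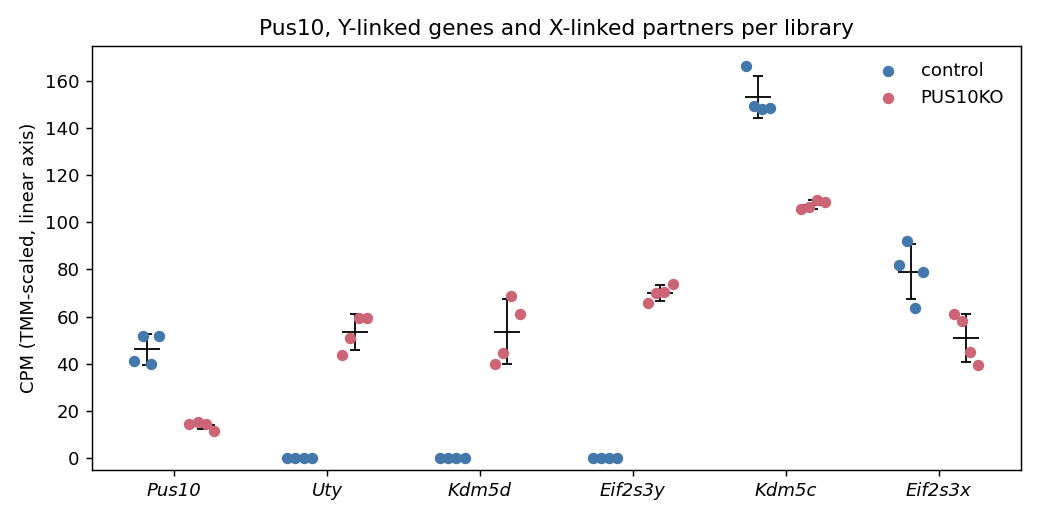
CPM on a linear axis for Pus10, 3 Y-linked genes and 2 X-linked genes, with 1 point per library and the mean and SD of each genotype. Pus10 lay between 11.5 and 15.2 CPM in the PUS10KO libraries and between 40.1 and 51.8 CPM in the control libraries, and the Y-linked genes had counts in the PUS10KO libraries and at most 2 counts over the control libraries.

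Across the transcriptome 703 genes rose and 847 fell in PUS10KO, 13% of the genes tested. Of these, 500 were at least 2-fold higher and 453 at least 2-fold lower, 953 in all. With the replicate block, which takes the differences between numbers out of the error, 2273 genes rose and 2368 fell, 39% of the genes tested. All 1550 genes called without it were among them. The count of genes that fell was 560 without PUS10KO 2 and 520 without PUS10KO 3. DESeq2 called 1146 genes that rose and 1287 that fell. For 20.3% of the tested genes the 4 control and the 4 PUS10KO values did not overlap, against 2.86% by chance.

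The genes with the highest fold changes included several with few or no counts in control. Besides the Y-linked genes these were Sorcs1, a sorting receptor (20.1 ± 7.77 CPM in PUS10KO, 0 counts in control, at least 562-fold higher, adjusted p = 0.000485), Ccdc184 (at least 218-fold higher), Hmcn1, a gene of an extracellular matrix protein (at least 164-fold higher), and Msx1, a homeobox transcription factor (3.82 ± 0.94 CPM, at least 109-fold higher). In PUS10KO libraries 1 to 4 Hmcn1 had 0.88, 2.23, 7.26 and 13.4 CPM (edgeR adjusted p = 0.0161). Ccdc184 had 7.82, 13.8, 4.73 and 2.81 CPM there (edgeR adjusted p = 0.0031). Csmd1 had 990 counts against 1 (ratio 991, exact 95% counting interval 178 to 39190) and Bnc1 670 against 1 (ratio 671, 120.0 to 26540). Agtr2, an angiotensin receptor, went from 0.074 ± 0.092 to 42.8 ± 41.1 CPM (log2 fold change 9.03, SE 1.33, adjusted p = 0.00286). It had 5.84 and 8.67 CPM in PUS10KO 1 and 2, and 75.8 and 81.0 CPM in PUS10KO 3 and 4. With 1 library left out, its log2 fold change ran from 8.53 to 10.06.

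Among the genes with the largest falls was Cyba, a subunit of the NADPH oxidase, with 27.9 ± 3.06 CPM in control and 1 count over the PUS10KO libraries (ratio 2208, exact 95% counting interval 396 to 87260, adjusted p = 3.2e-06). The fibroblast surface glycoprotein gene Thy1 had 21.8 ± 0.92 CPM in control and 2 counts in PUS10KO (ratio 862, 238 to 7122). Barx1, a homeobox gene, had 922 counts against 1 (ratio 921, 165 to 36410), and Lefty1, a secreted inhibitor of nodal signalling, 422 against 1 (ratio 422, 75.2 to 16690). The log2 fold change was -8.25 for Crip1, -7.72 for Ankrd1, -7.58 for the lysosomal protease gene Ctsk, -7.17 for Unc93b1, -6.27 for Ryr3 and -6.004 for Alkal1. Unc93b1 carries nucleic acid-sensing Toll-like receptors to endosomes, and went from 15.9 ± 5.74 to 0.10 ± 0.032 CPM (adjusted p = 2.76e-05). The calls of these 20 genes and of Pus10 held in all 8 fits that left out 1 library. In those fits the log2 fold change ran from -8.045 to -7.08 for Ankrd1, -6.70 to -5.39 for Ryr3 and -6.28 to -5.36 for Alkal1.

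Some interferon-stimulated genes rose in PUS10KO. Of 36 tested members of the type I interferon list 15 rose, 1 fell and 20 did not pass the test, and 23 rose and 1 fell when adjusted over the list alone. Ifi27l2a went from 4.66 ± 2.54 to 62.4 ± 37.2 CPM (log2 fold change 3.74, SE 0.51, adjusted p = 0.00203, edgeR's quasi-likelihood test). The 2'-5'-oligoadenylate synthetase-like gene Oasl2 went from 0.60 ± 0.74 to 22.1 ± 22.2 CPM (log2 fold change 5.16, adjusted p = 0.0076). With 1 library left out, the log2 fold change of Oasl2 ran from 4.20 to 6.50. Parp14 went from 3.48 ± 2.61 to 22.7 ± 8.99 CPM (log2 fold change 2.69, adjusted p = 0.00944). Oas1g had 186 counts in PUS10KO and 2 in control (ratio 93.1, exact 95% counting interval 25.4 to 775); it belongs to a family of near-identical copies, so its counts are uncertain. Ifit2, named after its values were seen, was the member that fell (log2 fold change -0.80, adjusted p = 0.014).

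The median log2 fold change of the list was 2.13 (camera adjusted p = 5.68e-09), with adjusted p = 0.637 with an estimated correlation and 0.081 by fry. Leaving out 1 library gave medians of 1.48 (without PUS10KO 1) to 2.57 (without control 1). The authors' deposited normalized values, fitted with the replicate block, gave a median of 1.09, against 2.12 for the counts with that block. The lowest deposited value was 5.13, on a scale that no source used here states. These medians are therefore not on the same measure. With the replicate block 32 members rose and 1 fell, with adjusted p = 0.168 with an estimated correlation and 0.00246 by fry. Between libraries of the same number the median differences were 2.16, 1.91, 1.85 and 2.04, and 31 of the 36 members were higher in PUS10KO in all 4 pairs. Levels also differed between numbers, since the list's median log2 CPM was 3.12, 0.52, 1.301 and 1.95 in control libraries 1 to 4 and 5.26, 3.30, 3.64 and 4.24 in PUS10KO libraries 1 to 4. The 4 libraries with the higher medians were also the 4 with at least 722 counts of each of Uty, Kdm5d and Eif2s3y.

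**Figure D2:**
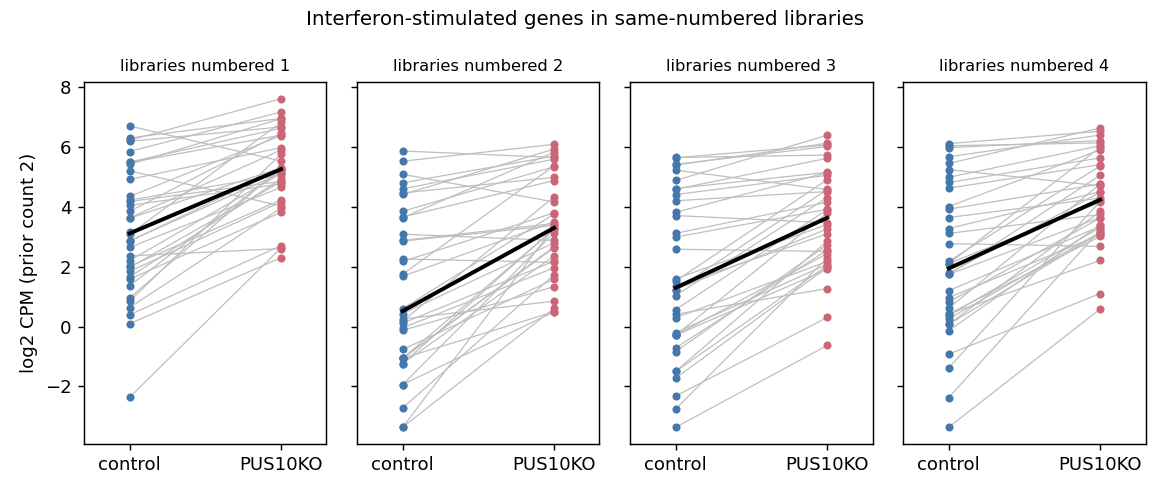
Log2 CPM (prior count 2) of the 36 tested type I interferon-stimulated genes in the control and PUS10KO library of each number, with 1 grey line per gene and the black line joining the medians. The medians rose from control to PUS10KO in each pair, from 3.12 to 5.26, 0.52 to 3.30, 1.301 to 3.64 and 1.95 to 4.24.

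Some genes of antigen presentation by MHC class I also rose. Of 16 tested members 10 rose, none fell and 6 did not pass the test. Adjusted over the list alone 13 rose, and with the replicate block 15 (median log2 fold change 1.00, camera adjusted p = 8.84e-11, adjusted p = 0.375 with an estimated correlation). Nlrc5, the transcriptional activator of this pathway, went from 1.15 ± 0.38 to 12.3 ± 4.64 CPM (adjusted p = 0.000623), the peptide transporter gene Tap1 from 14.01 ± 4.03 to 52.5 ± 17.2 CPM (adjusted p = 0.00312), and H2-K1 from 11.01 ± 4.27 to 103 ± 72.0 CPM (adjusted p = 0.00345). H2-Q4 had a log2 fold change of 5.76; it and H2-K1 belong to a multigene family whose reads can be split among copies, so their values are uncertain. In the list named interferon gamma-preferring genes, 6 of 11 rose, none fell and 5 did not pass. Which signal raised them was not tested, and the list does not tell interferon gamma from type I interferon. Adjusted over the list alone 8 rose, and with the block 9 (median log2 fold change 1.61, camera adjusted p = 6.8e-08, adjusted p = 0.358 with an estimated correlation). The chemokine gene Cxcl10 went from 0.18 ± 0.15 to 7.67 ± 2.90 CPM (log2 fold change 5.38, adjusted p = 0.000413), and Socs1, a feedback inhibitor of cytokine signalling, from 3.99 ± 1.16 to 9.75 ± 1.04 CPM (adjusted p = 0.00846).

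NF-kB and inflammatory cytokine genes showed 8 members that rose, 1 that fell and 14 that did not pass among 23 tested. Adjusted over the list alone 11 rose and 1 fell, and with the replicate block 15 rose and 1 fell (median log2 fold change 0.60, camera adjusted p = 1.13e-06, adjusted p = 0.167 with an estimated correlation). The adhesion molecule gene Icam1 went from 0.38 ± 0.29 to 43.6 ± 16.01 CPM (log2 fold change 6.79, SE 0.49, adjusted p = 9.06e-05). The neutrophil-attracting chemokine gene Cxcl1 went from 12.1 ± 4.07 to 75.2 ± 30.01 CPM (adjusted p = 0.00205), and Il1rl1, the interleukin 33 receptor, from 26.3 ± 5.04 to 120 ± 53.9 CPM (adjusted p = 0.00345). Among the members that rose, Cxcl10 also stands in the interferon gamma list and C3 in the complement list. Tnfaip3, an inhibitor of NF-kB named after its values were seen, was the member that fell (log2 fold change -1.06). Of 9 complement genes 3 rose, 1 fell and 5 did not pass, the same counts when adjusted over the list alone, and 7 rose and 1 fell with the block (median log2 fold change 0.74, camera adjusted p = 0.0152, adjusted p = 0.637 with an estimated correlation). C3 had a log2 fold change of 3.52 and C4b 3.13; Cd59a had -2.00 (adjusted p = 0.0421), a call lost in 6 of 8 fits that left out 1 library, all except those without control 3 or control 4 (adjusted p up to 0.109).

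Of 26 genes of nucleic acid sensing and signalling to interferon 4 rose, none fell and 22 did not pass, 5 rose when adjusted over the list alone, and 15 rose with the replicate block (median log2 fold change 0.32, camera adjusted p = 0.0162, adjusted p = 0.375 with an estimated correlation). The RNA sensor gene Ddx58, which encodes RIG-I, went from 34.4 ± 10.9 to 92.2 ± 26.3 CPM (log2 fold change 1.42, adjusted p = 0.0115). Sting1, the adaptor of cytosolic DNA sensing, had a log2 fold change of 1.07 (adjusted p = 0.0175, or 0.0504 without PUS10KO 3). Zbp1, a sensor of Z-form nucleic acids, had 3.49 (adjusted p = 0.0231, up to 0.0641 without control 3 or PUS10KO 1), and Dhx58 had 2.23 (adjusted p = 0.0407, up to 0.105, with the call kept in 2 of 8 fits, those without control 1 or PUS10KO 2). These genes except Sting1 also stand in the type I interferon list. The fits that left out 1 library had no replicate block. With the block and all 8 libraries, the adjusted p by edgeR's test was 6.65e-05 for Sting1, 4.41e-05 for Zbp1 and 0.00014 for Dhx58. With the block 39% of all genes tested passed.

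Lists of RNA modification and retrotransposon control were not called as lists. Of 34 retrotransposon silencing factors 2 rose, 2 fell and 30 did not pass (2 rose and 1 fell when adjusted over the list alone, 9 rose and 3 fell with the block; camera adjusted p = 0.496). Apobec3, a cytidine deaminase that restricts retroelements, had a log2 fold change of 1.36 (adjusted p = 0.0257), and Setdb1, a histone H3 methyltransferase, 0.41 (adjusted p = 0.0303). Dnmt3a, a DNA methyltransferase, had -0.68 (adjusted p = 0.0475) and Yy1 -0.48 (adjusted p = 0.0374), and both lie on chromosome 12. Apobec3 lost its call without control 1, control 2, PUS10KO 3 or PUS10KO 4 (adjusted p up to 0.0705), Setdb1 and Dnmt3a without any 1 library except control 4 (up to 0.0932 and 0.128), and Yy1 without any except control 4 or PUS10KO 2 (up to 0.0988). Those fits had no block. With the block and all libraries, the adjusted p by edgeR's test was 2.92e-05 for Apobec3, 0.00428 for Setdb1, 0.00286 for Dnmt3a and 0.00163 for Yy1.

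Among 35 tRNA modification and cleavage factors 2 rose, 3 fell and 30 did not pass, also when adjusted over the list alone, and 8 rose and 6 fell with the block (camera adjusted p = 0.711). Ang2, of the angiogenin ribonuclease family, went from 0.28 ± 0.20 to 1.57 ± 0.44 CPM (log2 fold change 2.47, adjusted p = 0.012), with near-identical copies that make its counts uncertain. Thg1l had a log2 fold change of 0.61, Adat2 -0.70, the tRNA methyltransferase gene Mettl1 -0.50 and Alkbh1 -0.63 (adjusted p = 0.0238, 0.0224, 0.0231 and 0.0404). Each of these 4 lost its call in at least 4 of 8 fits that left out 1 library: Thg1l without control 2, control 3, PUS10KO 1 or PUS10KO 2 (adjusted p up to 0.0709), Adat2 without control 2, PUS10KO 1, PUS10KO 3 or PUS10KO 4 (up to 0.0609), Mettl1 without control 2, 3 or 4 or PUS10KO 2 or 3 (up to 0.079), and Alkbh1 without any except control 3 or PUS10KO 1 (up to 0.113). Those fits had no block. With the block and all libraries, the adjusted p by edgeR's test was 0.00328 for Thg1l, 0.00195 for Adat2, 0.00542 for Mettl1 and 0.00119 for Alkbh1. Adat2 and Mettl1 lie on chromosome 10 and Alkbh1 on chromosome 12, whose median log2 fold changes were -0.25 and -0.60. Of 16 pseudouridine synthases Pus10 fell and 15 did not pass, with 6 rising and 1 falling under the block (camera adjusted p = 0.735). In the list of microRNA processing and Argonaute proteins edgeR's test called 0 of 17 members, 2 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0, and 3 rose and 1 fell with the block (camera adjusted p = 0.582). Ddx5 had a log2 fold change of 0.06 and Ddx17 0.08 (adjusted p = 0.835 and 0.861). tRNA fragments and retrotransposon transcripts were not analysed here.

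Some genes of the extracellular matrix and of contractile fibroblasts fell in PUS10KO. Of 35 collagen and matrix genes 10 fell, 1 rose and 24 did not pass, also when adjusted over the list alone, and 17 fell and 2 rose with the block (median log2 fold change -0.45, camera adjusted p = 0.000282, adjusted p = 0.637 with an estimated correlation). The collagen cross-linking enzyme gene Loxl2 went from 160 ± 59.1 to 16.6 ± 2.32 CPM (log2 fold change -3.28, SE 0.27, adjusted p = 0.000171), the elastic fibre gene Fbln5 from 371 ± 37.0 to 150 ± 23.7 CPM (adjusted p = 0.00081), and Fbln2 from 2377 ± 125 to 1139 ± 152 CPM (adjusted p = 0.00153). Thbs2, named after its values were seen, was the member that rose (log2 fold change 1.85). Of 17 contractile genes 5 fell, none rose and 12 did not pass, with 8 falling when adjusted over the list alone and 11 falling and 2 rising with the block (median log2 fold change -0.78, camera adjusted p = 0.00265, adjusted p = 0.728 with an estimated correlation). Acta2, smooth muscle actin, went from 10025 ± 5222 to 2248 ± 161 CPM (adjusted p = 0.00528), and Tagln from 3368 ± 1798 to 733 ± 253 CPM (adjusted p = 0.0102). Between libraries of the same number, 1 to 4, the median difference of the contractile list was -0.918, -0.939, -0.492 and -0.33. For the matrix list it was -0.637, -0.642, -0.423 and -0.233. The log2 difference of Acta2 was -2.51, -2.74, -1.48 and -1.24, and that of Tgfb3 was -3.24, -3.01, -0.80 and -0.69. Of 19 TGF-beta response genes 3 fell, none rose and 16 did not pass, also over the list alone, and 13 fell and 2 rose with the block (median log2 fold change -0.45, camera adjusted p = 0.0207, adjusted p = 0.685 with an estimated correlation). Itga11, a collagen-binding integrin, went from 98.8 ± 29.8 to 11.1 ± 5.09 CPM (adjusted p = 0.00107). Ltbp1 had a log2 fold change of -1.34 (adjusted p = 0.0202, or 0.0624 without PUS10KO 3), and the ligand gene Tgfb3 -2.41 (adjusted p = 0.0376), a call kept in 2 of 8 fits, those without control 3 or control 4 (adjusted p up to 0.10).

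**Figure D3:**
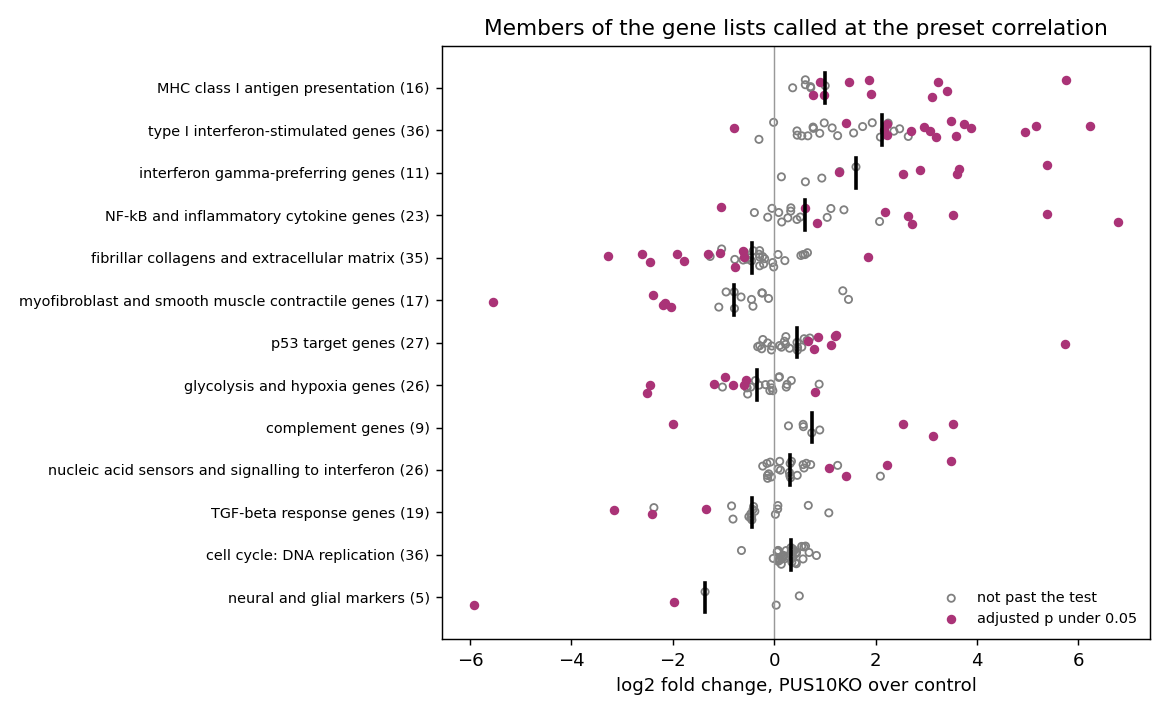
Log2 fold change of each tested member of 13 gene lists called at the preset correlation, with filled points for an adjusted p under 0.05, open points for the rest and a bar at each median. The medians were 2.13 for type I interferon-stimulated genes, 1.00 for MHC class I genes, -0.45 for extracellular matrix genes and -0.78 for contractile genes.

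The p53 targets included 7 members that rose and 20 that did not pass among 27, none that fell, and 8 that rose when adjusted over the list alone; with the block 14 rose and 1 fell (median log2 fold change 0.45, camera adjusted p = 0.0052, adjusted p = 0.358 with an estimated correlation). Perp went from 0.36 ± 0.41 to 19.6 ± 8.44 CPM (log2 fold change 5.73, adjusted p = 0.000944). With 1 library left out, the log2 fold change of Perp ran from 5.45 to 6.95. The cyclin-dependent kinase inhibitor gene Cdkn1a went from 50.5 ± 9.48 to 116 ± 25.0 CPM (log2 fold change 1.19, adjusted p = 0.00464). Ccng1 went from 621 ± 123 to 1138 ± 167 CPM (adjusted p = 0.0128). Of 26 glycolysis and hypoxia genes 7 fell, 1 rose and 18 did not pass, with 9 falling and 1 rising over the list alone and 13 falling and 3 rising with the block (median log2 fold change -0.34, camera adjusted p = 0.0113, adjusted p = 0.637 with an estimated correlation). Between libraries of the same number, 1 to 4, the median difference of this list was -0.032, -0.25, -0.575 and -0.566. P4ha1, a collagen prolyl hydroxylase, went from 509 ± 92.6 to 224 ± 29.4 CPM (adjusted p = 0.00198) and Ero1l from 134 ± 20.5 to 68.3 ± 4.14 CPM (adjusted p = 0.00191). Pfkp, named after its values were seen, was the member that rose (log2 fold change 0.81). The DNA replication list was called (median log2 fold change 0.33, camera adjusted p = 0.022, adjusted p = 0.946 with an estimated correlation) although edgeR's test called 0 of 36 members, 6 had an unadjusted p under 0.05, DESeq2 called 3 and limma voom 0. Its median difference was 0.661, 0.054, 0.169 and 0.331 between libraries of the same number, 1 to 4. With the block 17 rose and 1 fell, among them Rrm1 (log2 fold change 0.43, adjusted p = 0.278, or 0.00625 with the block) and Mcm6 (0.35, adjusted p = 0.195, or 0.0181 with the block).

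Markers of other cell types moved in both directions. Of 5 neural and glial markers 2 fell, also over the list alone, 3 did not pass, and 3 fell with the replicate block (median log2 fold change -1.36, camera adjusted p = 0.0348, adjusted p = 0.358 with an estimated correlation). The microtubule regulator gene Stmn2 went from 7.43 ± 4.00 to 0.12 ± 0.11 CPM (adjusted p = 0.00131) and Nes from 133 ± 58.8 to 33.8 ± 12.7 CPM (adjusted p = 0.00894). The other marker lists were not called. Of 3 epithelial markers Krt19 (log2 fold change -2.88) and Dsp (-2.97) fell and Trp63 (2.97) rose (camera adjusted p = 0.196); Dsp lost its call without control 3, PUS10KO 2 or PUS10KO 4 (adjusted p up to 0.0565) and Trp63 without PUS10KO 3 (0.0519). Of 3 mesothelial markers Bnc1 rose, Krt19 fell and 1 did not pass, and 2 fell with the block (camera adjusted p = 0.711). Of 4 macrophage markers Cd14 rose from 3.09 ± 0.86 to 12.8 ± 3.37 CPM (adjusted p = 0.00191) and 3 did not pass, of which 1 fell with the block (camera adjusted p = 0.711). Acta1 fell among 4 skeletal muscle markers (log2 fold change -5.32, or -5.69 to -4.06 with 1 library left out). Its adjusted p was 0.00716 by edgeR's test, or 0.0569 with limma voom. The camera adjusted p of this list was 0.735, and 1 of these markers rose with the block. Lpl fell among 7 adipocyte markers (log2 fold change -1.15, camera adjusted p = 0.711), where 4 fell and 1 rose with the block. Col2a1 rose among 4 chondrocyte and osteoblast markers (log2 fold change 1.67, adjusted p = 0.0361), with the call kept only without PUS10KO 4 among the 8 fits that left out 1 library (adjusted p up to 0.0837; camera adjusted p = 0.337), and 2 of these markers rose with the block. Of 4 endothelial markers edgeR's test called 0, 1 had an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0, 1 fell when adjusted over the list alone and 2 fell with the block; Flt1 had a log2 fold change of -2.11 (adjusted p = 0.0761, or 0.000321 with the block) and Egfl7 -0.15 (adjusted p = 0.737), and the camera adjusted p was 0.368.

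Called genes were unevenly spread over the chromosomes. Fisher's exact tests count genes as independent, although all come from the same 8 libraries, so their p-values do not measure the spread between samples. On chromosome 12, 179 of 405 tested genes passed the edgeR test, 44.2% against 11.9% elsewhere (odds ratio 5.84, two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 8.25e-55). Of these 167 fell and 12 rose, and 88.1% of the chromosome's genes had a log2 fold change below 0. Its median log2 fold change was -0.60, and between libraries of the same number it was -0.58, -0.63, -0.58 and -0.62. On chromosome 10, 126 of 576 genes passed (21.9% against 12.6%, adjusted p = 1.76e-08, median log2 fold change -0.25). Fewer genes than elsewhere passed on chromosomes 4, 7, 8 and 11 (6.8%, 8.2%, 8.2% and 10.2%; adjusted p = 2.44e-07, 2.58e-05, 0.00036 and 0.0234). With the replicate block chromosome 11 lost this call (38.8% of its genes called, adjusted p = 0.937). Chromosome 2 gained it (33.4%, adjusted p = 0.000585, against 0.491 without the block). Of the genes named above, 7 lie on chromosome 12, and their log2 fold changes relative to its median were -7.65 for Crip1, -1.81 for Tgfb3, -0.71 for Fbln5, 4.34 for Ifi27l2a, -0.08 for Dnmt3a, 0.12 for Yy1 and -0.02 for Alkbh1. Relative to the median of chromosome 10, the log2 fold change was -0.449 for Adat2, -0.243 for Mettl1, -0.93 for P4ha1 and 5.98 for Perp. With the block 4 chromosomes held more called genes than elsewhere. These were chromosomes 10 and 12 and also 6 (45.3%, adjusted p = 0.00513, against 0.161 without the block) and X (47.1%, adjusted p = 0.0032, against 0.626). In the libraries numbered 1 and 2 alone, an alternative chosen after the data were seen, edgeR's calls gave 0 such chromosomes, and 3 at an unadjusted p under 0.05.

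**Figure D4:**
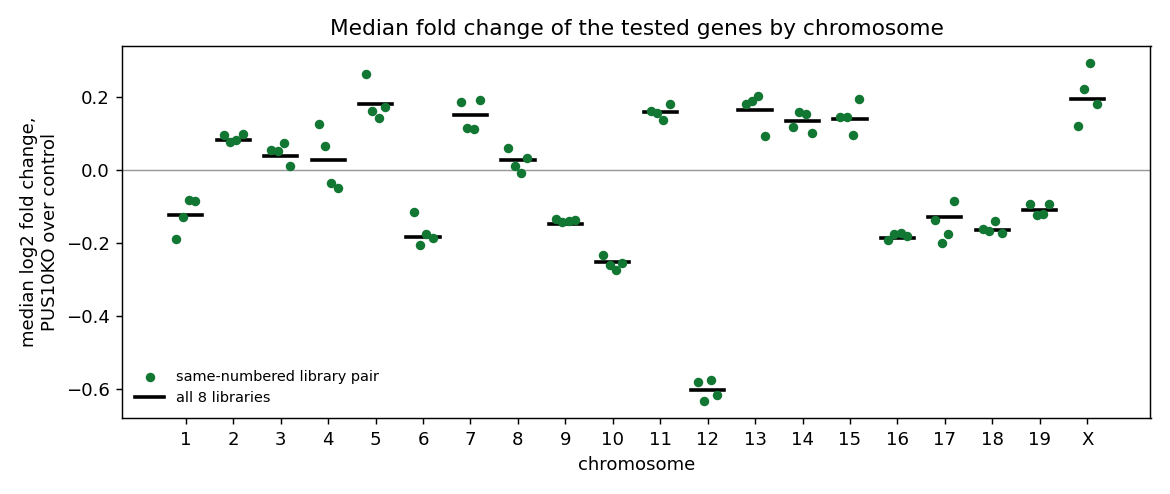
Median log2 fold change of the tested genes on each chromosome, PUS10KO over control, with 1 green point per pair of libraries of the same number and a black bar for all 8 libraries. Chromosome 12 lay at -0.60, with its pairs between -0.63 and -0.58, and chromosome 10 at -0.25.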

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

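Among the tests below, those of chromosome 12 along its length, of single pairs of libraries, of sex, of the origin of the cultures and of the size of the interferon-stimulated gene difference over other splits were chosen only after the result was seen; the rest were written before.

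In 7 groups of 4 libraries 1 value lay far from the other 3 on the log2 scale, of 243 groups examined, where about 12.2 would by chance. P4ha1 had 647.5 CPM in control 4 against 455 to 471 in the other control libraries. Itga11 had 55.1 CPM in control 1 against 105 to 119, and Kdm5c had 166.6 CPM in control 1 against 148 to 149. The histone genes H4c4 and H1f2 were lowest in control 1 as well, with 186 CPM against 484 to 554 and 289.9 CPM against 480 to 523. Rps29 had 39.66 CPM in PUS10KO 1 against 70.4 to 76.4, and Xpo1 had 470.1 CPM in control 2 against 301 to 308.

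The split of the libraries by genotype was compared with all 35 splits into 4 and 4. For the number of called genes 2 of 35 splits gave as many, so that count alone does not exclude chance: the genotypes gave 1550 and the highest other 2032, for numbers 1 and 2 against 3 and 4, which points to a structure of the samples by number. The 7 other splits that parted all 4 pairs called 0 genes by edgeR's test, with at most 261 at an unadjusted p under 0.05, and with the replicate block 0 against 4641 (at most 305 unadjusted); 8 such splits are too few for a share under 0.05. For genes changed at least 2-fold 1 of 35 splits gave as many (953, highest other 555). That share is under 0.05, but it treats the libraries as exchangeable and leaves out their pairing; among the 8 splits that part all pairs the highest other was 0, and these are too few. For gene lists called 22 of 35 splits gave as many (14, highest other 21), so chance is not excluded for that count.

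Genes of chromosome 12 were lower in PUS10KO, with a median log2 fold change of -0.60. GC content and gene length argued against as a cause, since the median was -0.59 once their trends were removed. A candidate explanation is a lower copy number of the chromosome in the PUS10KO than in the control cultures: the highest median of its 12 bins of 10 Mb was -0.48, so the shift ran along the whole chromosome, as that explanation needs. The counts give only the ratio of the genotypes, so a loss in PUS10KO and a gain in control cannot be told apart. Chromosome 10, with a smaller median of -0.25, was also below 0 in all of its 13 bins (highest -0.165), so a shift along a whole chromosome is not particular to chromosome 12. Except on chromosomes 4 and 8, the medians of the 4 pairs had 1 sign on every chromosome tested. The overall median was, for example, -0.19 on chromosome 16, 0.16 on chromosome 11 and 0.20 on X. DNA was not analysed here, and no effect of the knockout on a whole chromosome was tested.

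Interferon-stimulated genes were higher in PUS10KO, and the size of the difference exceeded that of every other split (median 2.13, highest other 2.05, 1 of 35 splits as large), whereas its camera statistic did not (z 6.26, highest other 13.83, 13 of 35 splits as large), so chance is not excluded for the latter. The first share also leaves out the pairing, and among the 8 splits that part all pairs, too few for a share under 0.05, the highest other median was 1.61. A response in 1 pair of libraries is argued against by the lowest pair median of 1.85. Once chromosome medians were subtracted, the list's median was 2.12. The chromosome median furthest from 0 was -0.60, too small to have removed the difference, so this test could not come out otherwise. It shows only that shifts of the genes' own chromosomes were smaller than the difference. Effects of copy number on genes of other chromosomes were not tested. Sex and genotype cannot be told apart here, because Y-linked genes had at least 50 counts in 4 of 4 PUS10KO libraries and more than 3 in none of the control libraries. The loss of Pus10, sex and other differences between the cultures may each contribute and stay open.

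In all, 23 genes were detected in 1 genotype only, with at least 50 counts in each library of 1 genotype and at most 3 in each of the other; 14 were found in PUS10KO and 9 in control, and no other split gave any. Their median was 11.62 CPM, but the selection itself allows no mean below 2.39 CPM, so this test, planned with a bound of 2 CPM, decides nothing about low counts. All 3 tested Y-linked genes were among them, which the knockout of a gene on chromosome 11 does not add, so a candidate explanation for part of the set is that the cultures came from different embryos or lines. Whether the 20 remaining genes, such as Sorcs1, Cyba and Thy1, follow the origin of the cultures or the knockout was not tested.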

How the results depend on the processing

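The fits without chromosomes 12, X and Y, of libraries 1 and 2 or 3 and 4 alone, of DESeq2 with the block, and of an estimated correlation with the block were chosen after the data were seen. The Pus10 log2 fold change kept its direction and call in all 23 fits (-1.84 to -1.44), and the type I interferon list was called at the preset correlation in each fit run (interferon-stimulated gene list median 1.09 on the deposited values, 1.48 without PUS10KO 1, up to 2.57 without control 1). Genes that rose and fell numbered 1146 and 1287 with DESeq2, 2273 and 2368 with the replicate block, 2545 and 2480 with GC and length offsets and the block, 2318 and 2329 with limma-trend on the deposited normalized values, and 2315 and 2353 with DESeq2 and the block; each of these 4 paired fits gave 4 chromosomes in excess. The 4 libraries numbered 1 and 2 gave 347 and 333 (0 chromosomes in excess by edgeR's calls, 3 at an unadjusted p under 0.05). Those numbered 3 and 4, as many, gave 1333 and 1506, so the number of samples alone does not account for the lower counts. The number of genes with at least a doubling or halving was 610 on the deposited values and 622 in libraries 1 and 2. Fold sizes on the deposited values, whose scale is not stated, are not on the same measure as those of the counts. Leaving out 1 library gave 520 to 728 genes that fell, with 560 without PUS10KO 2 and 520 without PUS10KO 3. Lists called were 1 with an estimated correlation and 0 with the block as well (6 at an unadjusted p under 0.05; fry with the block called 19). The type I interferon list (median 2.13) had adjusted p = 0.637 with an estimated correlation, 0.081 by fry, and 0.168 with an estimated correlation and the block (median 2.12). The cause was not tested for any of these.

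Of 3030 values for single genes and chromosome 12, 2745 were the same in direction and call, 211 lost a call, 42 gained one, 2 moved and 30 changed sign. No gene that changed sign was called. Leaving out 1 library, the log2 fold change ran from -0.257 to 0.008 for Egfl7, -0.014 to 0.388 for H4c4, -0.182 to 0.073 for H1f2, -0.507 to 0.164 for Hmgcs1, -0.301 to 0.161 for Cyp51, -0.018 to 0.111 for Ddx5, -0.044 to 0.247 for Ddx17, -0.115 to 0.397 for Top2a and -0.721 to 0.046 for Anln. Cyp51 (-0.06) was 0.009 with limma voom, 0.002 with the block, 0.005 with offsets and the block, 0.006 on the deposited values and with DESeq2 and the block, and 0.035 in libraries 1 and 2. H1f2 (-0.03) was 0.001 on the deposited values and with DESeq2 and the block, and 0.003 in libraries 3 and 4. In libraries 1 and 2 Egfl7 was 0.037 and Ddx17 -0.101. The cause was not tested. The replicate block changed no call of a named gene, list or chromosome other than those given beside them. The fits that left out 1 library had no block, so differences between numbers stayed in their error. In the simulation, which used the depths and the spread of the fit without the block, 40.3% of 2-fold changes were called.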

Other observations

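Several further groups held members that moved in opposite directions. Of 13 imprinted genes 3 rose and 2 fell, also when adjusted over the list alone, and 8 did not pass; with the replicate block 4 rose and 3 fell (camera adjusted p = 0.711). Dlk1, a growth-related gene of chromosome 12, went from 11.1 ± 7.08 to 76.7 ± 49.3 CPM (edgeR adjusted p = 0.0106), against the fall of that chromosome as a whole, and Peg10 from 7.61 ± 2.69 to 28.7 ± 7.17 CPM (adjusted p = 0.00274). Cdkn1c had a log2 fold change of 1.94, Ndn -1.95, and Igf2r, named after its values were seen, -1.14. Of 19 matrix metalloproteinases and inhibitors 2 rose and 3 fell (2 and 6 over the list alone, 8 and 6 with the replicate block; camera adjusted p = 0.917). The gelatinase gene Mmp9 went from 0.048 ± 0.068 to 3.57 ± 1.81 CPM (adjusted p = 0.00119), and Mmp3 had 87 counts against 3 (ratio 29.0, exact 95% counting interval 9.61 to 144). Mmp23 had a log2 fold change of -3.37 and the collagenase gene Mmp14 -0.95 (adjusted p = 0.0313), a call lost without control 1, 3 or 4 or PUS10KO 1 or 2 (adjusted p up to 0.0763); Mmp17, named after its values were seen, had -2.43. Of 15 senescence genes 3 rose and 2 fell (5 and 2 over the list alone, 6 and 5 with the block; camera adjusted p = 0.711). Cdkn2b, which encodes the cyclin-dependent kinase inhibitor p15, went from 76.7 ± 32.6 to 8.56 ± 2.29 CPM (adjusted p = 0.000756) while Cdkn1a rose, and Igfbp7 went from 413 ± 16.5 to 226 ± 21.8 CPM (adjusted p = 0.00153).

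Of 24 amino acid response genes 2 fell (1 over the list alone; 10 fell and 2 rose with the block), and the camera adjusted p was 0.10, or 0.0172 with the block at the preset correlation, a call lost with an estimated correlation and the block (adjusted p = 0.86). The 2 that fell were Slc7a3 (log2 fold change -2.24, adjusted p = 0.0188), lost without PUS10KO 2 or 3 (up to 0.0554), and Ddit3 (-1.22, adjusted p = 0.0489), kept only without control 1 (up to 0.124). Of 16 heat shock genes Hspb1 (-1.81) and Hspa8 (-0.65) fell and Hspb8 (0.87) rose (2 and 2 over the list alone; 4 fell and 2 rose with the block; camera adjusted p = 0.711). Hspb1 lost its call without PUS10KO 3 (adjusted p = 0.0514), Hspa8 without control 2, PUS10KO 3 or PUS10KO 4 (up to 0.0779), and Hspb8 without control 1, 2 or 3 or PUS10KO 2 or 4 (up to 0.0666). Of 20 aminoacyl-tRNA synthetases Wars (-0.90) and Nars (-0.86) fell, also over the list alone, and 6 fell and 1 rose with the block (camera adjusted p = 0.326); Wars lies on chromosome 12, and Nars had an adjusted p of 0.05 without PUS10KO 3. Of 78 cytosolic ribosomal proteins Rpl29 (-0.89), Rplp1 (-0.84), Rps7 (-0.65) and Rps29 (-0.71) fell (3 over the list alone; 19 fell and 2 rose with the block; camera adjusted p = 0.472); Rps7 and Rps29 lie on chromosome 12, and the many pseudogenes of this family make their counts uncertain. Rps7 lost its call without control 3 or PUS10KO 2 (up to 0.0568) and Rps29 without any 1 library except PUS10KO 1 (up to 0.102). Of 42 nuclear oxidative phosphorylation genes Atp5d fell (-0.41, kept only without control 1, up to 0.0986), none over the list alone, and 8 fell and 2 rose with the block (camera adjusted p = 0.472). Atp5d lies on chromosome 10, and its log2 fold change relative to that chromosome's median was -0.16. Of 19 endoplasmic reticulum chaperones Sel1l fell (-0.67, on chromosome 12, kept without control 2 or PUS10KO 4, up to 0.0662), 1 over the list alone and 5 with the block (camera adjusted p = 0.373).

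Of 16 YAP and TEAD targets Ankrd1 fell and Foxf2 rose (log2 fold change 1.27, adjusted p = 0.0196, or 0.058 without PUS10KO 2), also over the list alone; with the block 8 fell and 1 rose (camera adjusted p = 0.326, or 0.000557 with the block at the preset correlation, a call lost with an estimated correlation and the block, adjusted p = 0.734). Of 13 Hox genes Hoxa11 (-1.39) and Hoxa10 (-0.89, adjusted p = 0.0494, kept without control 1 or PUS10KO 3, up to 0.127) fell, also over the list alone, and 3 fell and 1 rose with the block (camera adjusted p = 0.711).

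In 5 further lists edgeR's test called 0 members, also when adjusted over the list alone. For 50 replication-dependent histones 0 had an unadjusted p under 0.05 and DESeq2 and limma voom called 0, while 3 rose with the block (camera adjusted p = 0.424); H4c4 had a log2 fold change of 0.23 (adjusted p = 0.717) and H1f2 -0.03 (adjusted p = 0.96). For 32 mitosis genes these counts were also 0, with 4 that rose and 1 that fell with the block (camera adjusted p = 0.711); Top2a had 0.15 (adjusted p = 0.852) and Anln -0.37 (adjusted p = 0.629, or 0.0105 with the block). For 7 mitochondrially encoded mRNAs they were 0 again, and 1 rose with the block (camera adjusted p = 0.711); mt-Co1 had 0.30 (adjusted p = 0.239, or 0.0256 with the block) and mt-Nd1 -0.09. Of 22 cholesterol synthesis genes 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0, and 7 fell and 1 rose with the block (camera adjusted p = 0.472); Hmgcs1 had -0.17 (adjusted p = 0.87) and Cyp51 -0.06 (adjusted p = 0.936). Of 17 immediate early genes 2 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0, and 2 rose and 2 fell with the block (camera adjusted p = 0.917); Junb had 0.38 (adjusted p = 0.432, or 0.0163 with the block) and Myc 0.53 (adjusted p = 0.564, or 0.00233 with the block).

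Ccnb1ip1, named after its values were seen, had 7730 ± 1640 CPM in control and 10412 ± 1997 CPM in PUS10KO (log2 fold change 0.43, adjusted p = 0.223, or 0.0044 with the block). In the annotation it overlaps Rpph1, the gene of the abundant RNase P RNA, on the same strand, so its counts cannot be assigned to either gene.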
